A study of Mus musculus with 20 samples.

How the data were processed

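Per the labels, mouse E14 wild-type embryonic stem cells were treated with DRB at 100 µM or triptolide at 10 µM, and RNA was labelled for 10 min with 150 µM 4-thiouridine or left unlabelled as a background control. Samples were grouped by the drug, time and labelling that the labels state, which gave 10 labelled and 10 unlabelled samples in 10 groups of 2 replicates. Per the submitters' processing notes, reads were aligned with Bowtie to GRCm38/mm10. Per the file headers, gene identifiers are those of Ensembl 72 for GRCm38. The deposited values are a signal in reads per kilobase of gene, and the name of the deposited sheet says that negative values were set to 0 and that genes are protein-coding. The deposited table holds 1 column for each of the 5 conditions, and neither the labels nor the headers say how replicates were combined, how unlabelled libraries were subtracted or whether read numbers were equalised. Library sizes per sample and the use of strand in counting are not given in the sources used here.

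Within each gene the 5 deposited values were whole multiples of 1 common step, equal to 1000 divided by the gene's length in bases, so net reads were recovered by dividing each value by that step. Of 17512 genes with signal, 17187 received a length: 10379 had the span in GENCODE M21 exactly, 6353 a length from the step within 20% of it, and 455 a length from the step alone. For 325 genes no length was found and no net reads are given. All recovered values, 100%, were whole within 0.01 reads, which follows from how the lengths were found and tests nothing. A length from the step alone may be a fraction of the true length, a case that the simulated lengths do not cover. Of 22556 genes, 21800 were in the annotation and 756 were not, no identifier was repeated, and 27 gene names that a spreadsheet had turned into dates were restored by identifier. Gene positions are from GENCODE M21, and 430 tRNA genes are from the RefSeq annotation of GRCm38.p6.

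Genes with a value above 1 in at least 1 of the 5 conditions were compared, 8773 in number, on the scale log2(value + 1) with no further scaling. The filter had been fixed as a value above 1 in at least 2 libraries and was translated to 1 condition. The planned limma test on replicates and the camera test on lists could not be run on 1 column per condition, and the values are given with no test, as had been planned for that case. A difference of at least 1 on the log2 scale is the size rule for counts of lower and higher genes. Ratios of net reads carry the exact (Clopper-Pearson) 95% interval of a ratio of 2 Poisson counts, which leaves out replicate spread and the subtraction of background and therefore understates the error. A gene with no net reads is said to be listed at 0, with no fold, because negative values had been set to 0.

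The 7 comparisons were each drug time with no drug, the later with the earlier time of each drug, and DRB with triptolide at 2 h. Of 19 gene lists, 17 with at least 3 members were compared with 10000 random lists matched on mean level in 20 bins, which makes 119 comparisons, of which 20 lay outside the central 95% and 5.95 would by chance. In 11 of the 20, at least 50% of members were listed at 0 in a column, so that the median follows the level in the other column, and these calls are not used. As an alternative added after the data were seen, the percent of net reads a list kept was compared with 10000 lists matched on the reference column in 40 bins, in the 5 comparisons whose reference is not a triptolide column; 10 of 85 lay outside the central 95%. Neither kind of random list was matched on gene length. Lists were also summed without the member with most reads in the treated or later column. The lists are pluripotency factors, PRC2 and PRC1 subunits, developmental Polycomb targets, immediate early genes, replication-dependent histones, cytosolic ribosomal proteins, p53 targets, P-TEFb and its regulators, TFIIH and RNA polymerase II subunits, heat shock and proteotoxic stress, glycolysis, cell cycle, long genes, primitive endoderm, fibroblast and feeder, and neural markers. Mitochondrially encoded genes have no row in the table, and 1 member of the Zscan4 and 2-cell-like list, Eif1a, passed the filter, so these lists were not tested.

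Genes were named by a rule: the 10 lowest and 10 highest ratios per comparison among genes whose higher value was at or above the median, with genes listed at 0 ranked by their reference value where more than 10 were, up to 4 members per list by size of the log2 difference, and always Pou5f1, Sox2, Nanog, Myc, Ezh2, Suz12, Eed, Jarid2, Hexim1, Cdkn1a, Actb and Gapdh. Where the planned rule ranked list members by p, the size of the difference was used, as no p exists. The lists, comparisons, filter, size of pseudocount and naming rule were fixed before the data were examined, and the size rule was fixed once the table proved to hold 1 column per condition. The alternatives were pseudocounts of 0.1 and 10, no filter, a value above 10, scaling to equal medians and quantile normalization. The last 2, called rescalings, assume that most genes are unchanged. A fall in most genes was possible, so values without rescaling were fixed as the main choice. A setting with at least 20 net reads in 1 condition was added after the data were seen. Equal medians are those of the values above 0 in each column, from 15238 genes without drug and 7981 after 1 h of triptolide. Because these genes differ, the median log2 difference from no drug over the genes compared was still -0.29 for DRB 2 h and -1.56 for triptolide 1 h after this scaling.

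The steps were tested on simulated data. Of 3000 simulated gene lengths 99.97% were recovered exactly. With the read numbers of the no-drug column in both simulated columns, 87.0% of 200 genes changed 4-fold passed the size rule against 1.21% of unchanged genes; the lower read numbers of the drug columns were not simulated. Of 200 unshifted lists in DRB 2 h against no drug, 4.5% lay outside the central 95%. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The promoter CpG class of genes was left out, because no genome sequence was at hand, and labelled and unlabelled libraries were not compared, because the table used here has no unlabelled column.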

Results

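Mouse E14 wild-type embryonic stem cells grown in serum were treated with 1 of 2 drugs that block RNA polymerase II, and newly made RNA was measured. DRB, given at 100 µM for 2 h or 5 h, inhibits the kinases that release the polymerase into elongation, and triptolide, given at 10 µM for 1 h or 2 h, blocks initiation through the TFIIH helicase XPB. RNA was tagged for 10 min with 4-thiouridine at 150 µM, and the tagged fragments were captured and sequenced, a method called in vivo transcription capture (iTC-seq). The 20 samples form 10 groups of 2 replicates, with 5 conditions that each have a labelled group and an unlabelled background group. The deposited table gives 1 column per condition for 22556 genes, in reads per kilobase of gene with negative values set to 0. No value therefore has a replicate error or a test, and differences are given as higher or lower values. Intervals in brackets are exact 95% Poisson intervals of a ratio of net read numbers, which cover counting error only.

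The recovered net reads summed to 1249046 without drug, 334399 after 2 h and 95550 after 5 h of DRB, and 73975 after 1 h and 62427 after 2 h of triptolide. These sums were 26.8%, 7.65%, 5.92% and 5.00% of the sum without drug. Because the table does not say whether read numbers were equalised, a difference in depth between columns cannot be separated from a difference in transcription. Rescaling columns to equal medians or quantiles assumes that most genes are unchanged, and a fall in most genes was possible here. A value that turns higher under a rescaling therefore shows dependence on scale and is not by itself evidence of a rise. As a background class, 1108 olfactory receptor genes, known for their use in olfactory neurons, averaged 0.00626 reads per kb without drug and from 0.00486 to 0.0149 with drug. Over all genes the mean was 2.98 reads per kb without drug, 0.947 and 0.224 after 2 h and 5 h of DRB, and 0.123 and 0.138 after 1 h and 2 h of triptolide. The 10 genes with most reads held 3.74% of net reads without drug and from 5.44% to 8.93% with drug.

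**Figure D1:**
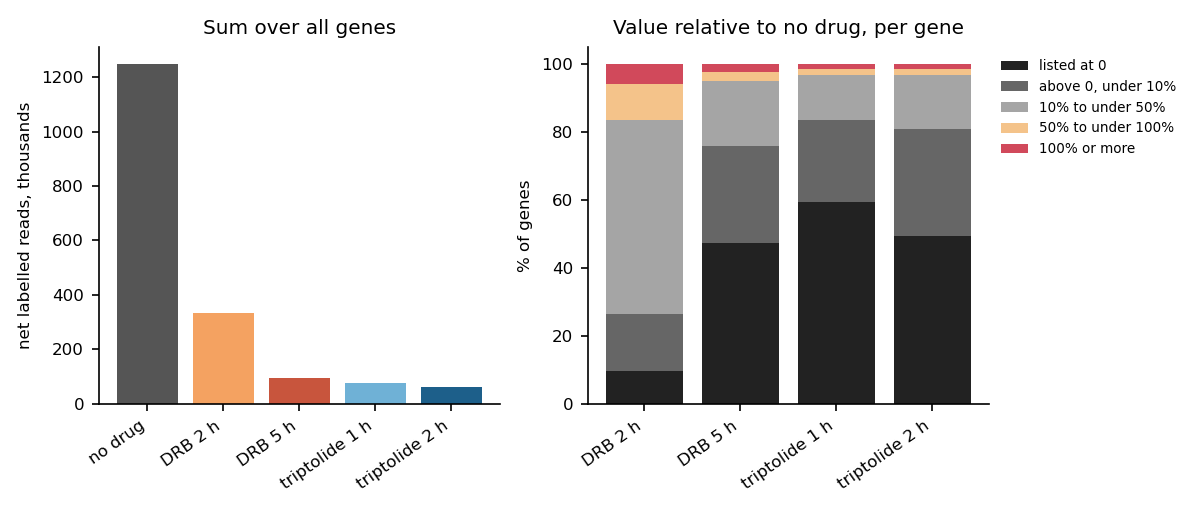
The left panel plots net labelled reads (axis in units of 1000) summed over all genes in each of the 5 conditions, and the right panel plots the percent of 8560 genes in each class of value relative to no drug. The sums after drug lie between 5.00% and 26.8% of the sum without drug, and the share of genes listed at 0 is 9.47% after 2 h of DRB and 59.3% after 1 h of triptolide.

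The first comparison, DRB for 2 h against no drug, addresses how far labelled RNA is reduced soon after elongation is blocked, in a series whose title concerns Polycomb repressive complex 2 (PRC2) and silenced CpG-island genes. Pou5f1, the core pluripotency factor Oct4 (chromosome 17, 35506018 to 35510772, GRCm38), was at 11.2 reads per kb after 2 h of DRB and 62.5 without drug, or 17.9% (13.1 to 24.1). Nanog, another core factor (chromosome 6, 122707489 to 122714633), was at 7.98 against 30.0 reads per kb, or 26.6% (19.5 to 35.8). Sox2, their partner (chromosome 3, 34650405 to 34652461), was at 52.5 against 69.6 reads per kb, or 75.4% (59.6 to 95.4), and was higher than without drug once columns were scaled to equal medians or quantiles. Replication-dependent histone genes, read in S phase, kept 82.2% (78.0 to 86.7) of their net reads, with 11 of 59 members lower by at least 1 on the log2 scale, 4 higher and 44 within that size. Of 8773 genes above 1 read per kb in at least 1 condition, 5800 were lower by at least 1 log2 unit of value plus 1 and 193 were higher, with a median log2 difference of -1.27. Among genes with at least 20 net reads in 1 condition 5028 were lower and 48 higher, and a pseudocount of 10 gave 644 and 25.

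Among 8560 of these genes with signal without drug, the median level after 2 h of DRB was 20.0% of the level without drug, with quartiles at 9.52% and 36.7%, and 511 genes were at or above it; the median level was 73.5% with equal medians and 81.6% with equal quantiles. The lowest genes by ratio included Tmsb10, an actin-binding peptide gene at 30.0 reads per kb without drug, and Yars2, a mitochondrial tRNA synthetase gene at 16.8, both listed at 0 with DRB. Foxd3, a stem cell transcription factor, was listed at 0 against 19.8 reads per kb. The pluripotency list kept 48.7% (47.4 to 50.04) of its net reads, with 19 of 31 members lower, 1 higher and 11 within the size rule. Members named for the size of their difference, which do not stand for the list, were Fgf4, a growth factor gene at 15.3% of no drug, Gdf3, a TGF-beta family ligand gene at 11.3%, and L1td1, an RNA-binding protein gene at 16.1%, while Dppa5a had 7 net reads with DRB and was listed at 0 without. The list's median, -1.34, turned positive under both rescalings. Esrrb held 2007 of the list's 8136 net reads with DRB, and without it the list kept 43.2% (41.9 to 44.5). Random lists matched on the level without drug kept 26.9%, with a central 95% from 18.6% to 42.7%. Myc, a growth regulator, was at 64.6% (47.5 to 87.5) of no drug and was higher than without drug under both rescalings.

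Genes of the PRC2 list had a median log2 difference of -1.22 after 2 h of DRB, with 7 of 10 members lower, and those of the PRC1 list had -1.59, with 10 of 13 lower; these lists kept 25.1% and 20.9% of their net reads. Suz12, a core PRC2 subunit (chromosome 11, 79993106 to 80034123), was at 14.5% of no drug, and Jarid2, an accessory subunit (chromosome 13, 44729474 to 44921643), was at 22.4% (20.3 to 24.7). Ezh2, the methyltransferase (chromosome 6, 47530139 to 47595341), was at 54.7% (40.7 to 73.1), and Eed, which binds methylated histone H3 (chromosome 7, 89954654 to 89980983), at 48.3%; both were higher than without drug under both rescalings. Cbx7, a PRC1 subunit gene, was at 15.8%. Of 50 developmental Polycomb targets only 8 passed the filter, so their values do not stand for the class, here or in the later comparisons. These had 5 of 8 members lower, a median of -1.17 and 17.0% of net reads, 43 against 253. Otx2 was at 0.301 against 3.51 reads per kb and Pax6 at 17.3% of no drug.

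After 2 h of DRB the 78 cytosolic ribosomal protein genes kept 30.2%, with 68 lower, and Rplp1, a stalk protein gene, was at 4.55% (2.15 to 8.52) of no drug and Rps6 at 6.69%. Without Rps14 the list kept 26.4%. Immediate early genes kept 40.9%, or 32.6% without Junb, with 14 of 23 lower and 2 higher, and Ctgf, a growth factor-responsive gene, was at 7.53%. The p53 target list kept 50.02%, with 12 of 19 lower and 1 higher, against 25.2% (central 95% from 16.0% to 47.8%) in lists matched on level, and kept 33.1% without Mdm2; its median, -1.29, turned positive under both rescalings. Gadd45a, a stress-induced member of that list, was at 6.0% and Cdkn1a, a cell cycle inhibitor, at 26.0%. Cell cycle genes kept 21.97%, with 24 of 28 lower and Cdk1, the mitotic kinase, at 9.24%, and glycolysis genes kept 16.8%, with Pkm at 10.6% and Gapdh at 10.0% (7.62 to 13.0). Actb, the gene of beta-actin, was at 16.5%. Genes of the kinase P-TEFb and its regulators kept 24.2%, with 19 of 22 lower, Hexim1, its inhibitor, at 21.9% and Mepce, a capping enzyme of its 7SK partner, at 2.36% (0.481 to 7.06). TFIIH and RNA polymerase II subunit genes kept 27.2%, with 17 of 21 lower and Polr2l at 0.917 against 25.1 reads per kb. Heat shock genes kept 24.3%, with the 18-member list's regulator Atf4 at 9.72%. Long genes kept 23.2% (6 of 40 members past the filter) and primitive endoderm markers 24.6% (3 of 15). Neural markers kept 25.4% (5 of 15) and fibroblast and feeder markers 48.4% (3 of 15, with 220 of 257 net reads in Fn1). The medians of these 3 marker lists turned positive under both rescalings. So few members do not stand for their classes, here or in the later comparisons.

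A smaller set of genes had higher values after 2 h of DRB. Colec11, a collectin gene (chromosome 12, 28594173 to 28623377), had 347 net reads against 2, a ratio of 174 (47.7 to 1438), and Rbbp8nl (chromosome 2, 180277646 to 180289879) was at 23.5 against 0.736 reads per kb, a ratio of 31.9 (16.6 to 70.5). Fcgrt, the neonatal Fc receptor gene, had a ratio of 20.6 (9.73 to 52.1) and Vwce of 15.9. Hist1h2bl was at 5.26 reads per kb and listed at 0 without drug. Hist2h2ab, also a histone gene, was at 29.3 against 102 reads per kb, and was higher than without drug with columns scaled to equal medians. Chosen after their values were seen, Mdm2, the ubiquitin ligase that restrains p53 (chromosome 10, 117688875 to 117710758), was at 23.7 against 10.9 reads per kb and Junb, an AP-1 factor, at 51.1 against 13.1.

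Against 10000 random lists matched on mean level, the histone list's median of -0.23 lay above the central 95% (random median -1.79), although it is positive under both rescalings, and the cell cycle median of -1.99 lay below it (random median -1.53), but inside it among values above 10. Lists matched on the level without drug kept 27.7% (central 95% from 20.4% to 38.3%) of net reads beside the 82.2% of histones, while the 21.97% of the cell cycle list lay within such lists. The medians of the other 15 lists lay inside. Scaling all columns to equal medians gave 2104 lower and 1080 higher genes, and quantile normalization gave 684 and 637, so the number of lower genes rests on the deposited scale. A pair of columns simulated with no change, both at the read numbers of the no-drug column, gave at most 141 genes past the size rule, which does not cover a difference in depth.

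**Figure D2:**
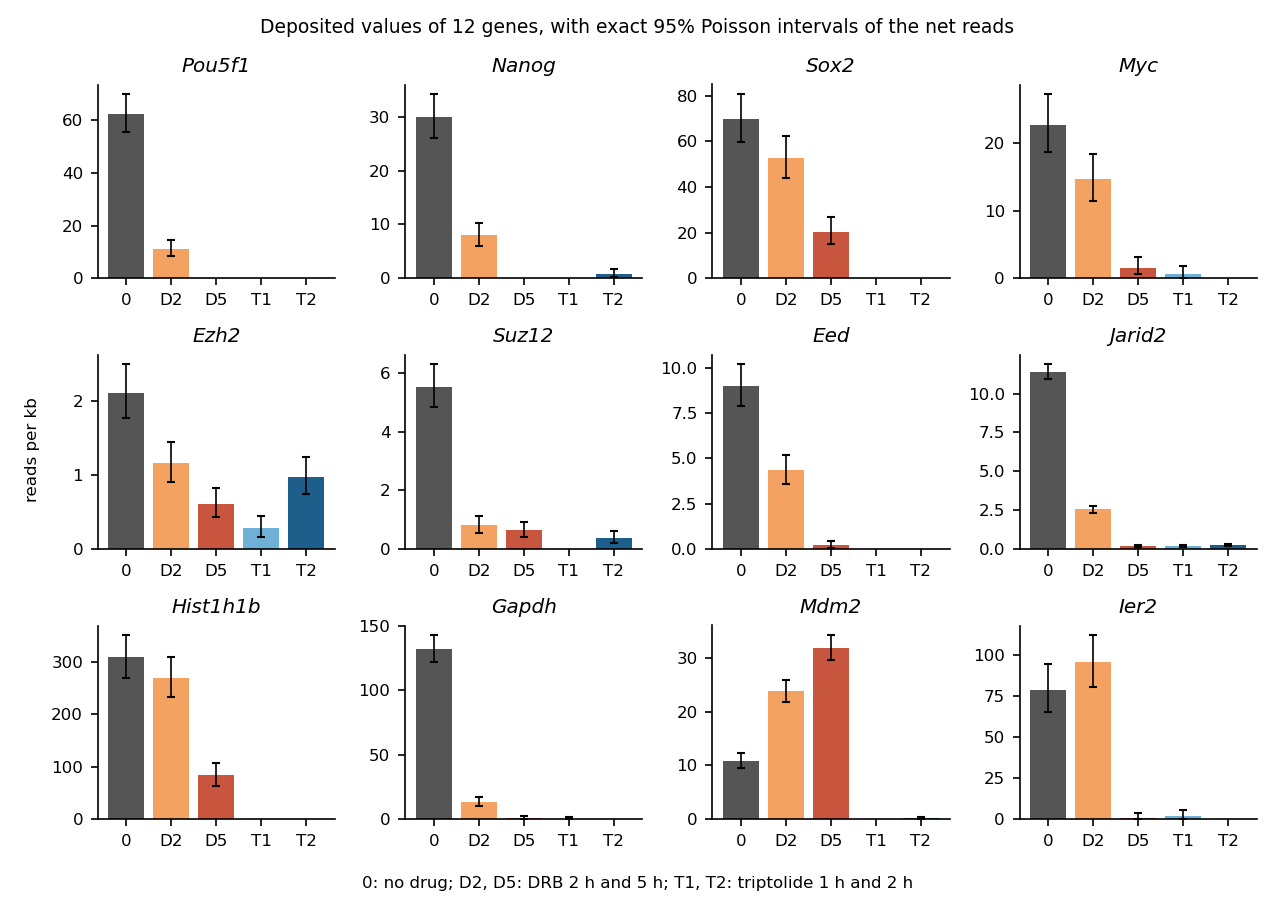
Bars show deposited values in reads per kb of 12 genes without drug (0), after 2 h or 5 h of DRB (D2, D5) and after 1 h or 2 h of triptolide (T1, T2), with lines for exact 95% Poisson intervals of the net reads. Pou5f1 is at 62.5 without drug and at 0 from 5 h of DRB and in both triptolide columns. Ezh2 is at 2.11 and 0.968 without drug and after 2 h of triptolide. It is higher with triptolide only under the rescalings, which assume that most genes are unchanged. The panels of Hist1h1b, Mdm2 and Ier2 were chosen after their values were seen.

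After 5 h of DRB, the second comparison with no drug, Pou5f1, Nanog and Actb were listed at 0, and the median gene was at 1.24% of its level without drug (10.9% with equal medians and 32.5% with equal quantiles), with 4049 of 8560 genes listed at 0. Sox2 was at 20.4 against 69.6 reads per kb, or 29.2% (20.9 to 40.3), and Suz12 at 11.5%, both higher than without drug under both rescalings. Ezh2 was at 28.5% and Cdkn1a at 19.2%, which also turned higher under both. Jarid2 was at 1.46% and Eed at 2.12%. Of 8773 genes, 7503 were lower by at least 1 log2 unit and 90 were higher, with a median of -1.86. A minimum of 20 net reads in 1 condition left 6434 lower and 28 higher, and a pseudocount of 10 left 1314 and 1. Scaling to equal medians gave 5039 lower and 883 higher, and quantile normalization 2300 and 1110.

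Ribosomal protein genes kept 7.72% of net reads after 5 h of DRB, with all 78 members lower, and Rps12 and Rps9 listed at 0 against 233 and 208 reads per kb. Rps14 held 1064 of the list's 2684 net reads with DRB, and without it the list kept 5.21%. Pluripotency genes kept 3.37%, with 29 of 31 lower and 20 listed at 0, and PRC2 genes kept 3.93% with 9 of 10 lower, PRC1 genes 4.35% with 12 of 13 lower. Histone genes kept 22.6% (20.8 to 24.6), with 50 of 59 lower; Hist1h2bh was at 2.30 against 113 reads per kb and Hist1h3e was listed at 0 against 44.3. Cell cycle genes kept 1.65%, with all 28 lower, and Cdk1 was at 0.123 against 47.8 reads per kb. Glycolysis genes kept 0.704%, heat shock genes 1.72%, with Hsp90ab1 listed at 0 against 130 reads per kb, and P-TEFb and TFIIH genes 4.07% and 4.597%. Immediate early genes kept 9.54%, with 19 of 23 lower and 1 higher, and Ier2, a growth factor-induced gene, was at 0.657 against 78.9 reads per kb. Developmental Polycomb targets kept 5.93%, long genes 4.65%, primitive endoderm markers 2.99%, neural markers 2.02% and fibroblast and feeder markers 0.942%.

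p53 targets kept 35.5% after 5 h of DRB, with 16 of 19 lower and 1 higher, but 9.58% without Mdm2. Bax and Trp53 were listed at 0 against 38.2 and 27.5 reads per kb. The p53 median, -1.95, lay above the central 95% of matched random lists (random median -3.17) and inside it under both rescalings, with a median of -0.32 with equal medians and 0.33 with equal quantiles. The histone median, -1.98, lay above it too (random median -4.38) and turned positive under both rescalings. Beside the 22.6% of net reads that histones kept, lists matched on level kept 3.603% (central 95% from 1.80% to 10.3%), and beside the 0.704% of glycolysis genes 3.69% (1.04% to 13.4%); without Mdm2 the p53 list lay within such lists. Without the member with most reads, glycolysis genes kept 0.229%, cell cycle genes 1.03%, pluripotency genes 1.89%, developmental targets 9.65% and fibroblast and feeder markers 0. Colec11 was at 80 times (21.8 to 666) and Rbbp8nl at 13.8 times its value without drug, and Nlrp12 at 3.27 times. St5 was at 3.07 times (2.64 to 3.59). Chosen after its values were seen, Mdm2 was at 31.8 against 10.9 reads per kb.

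**Figure D3:**
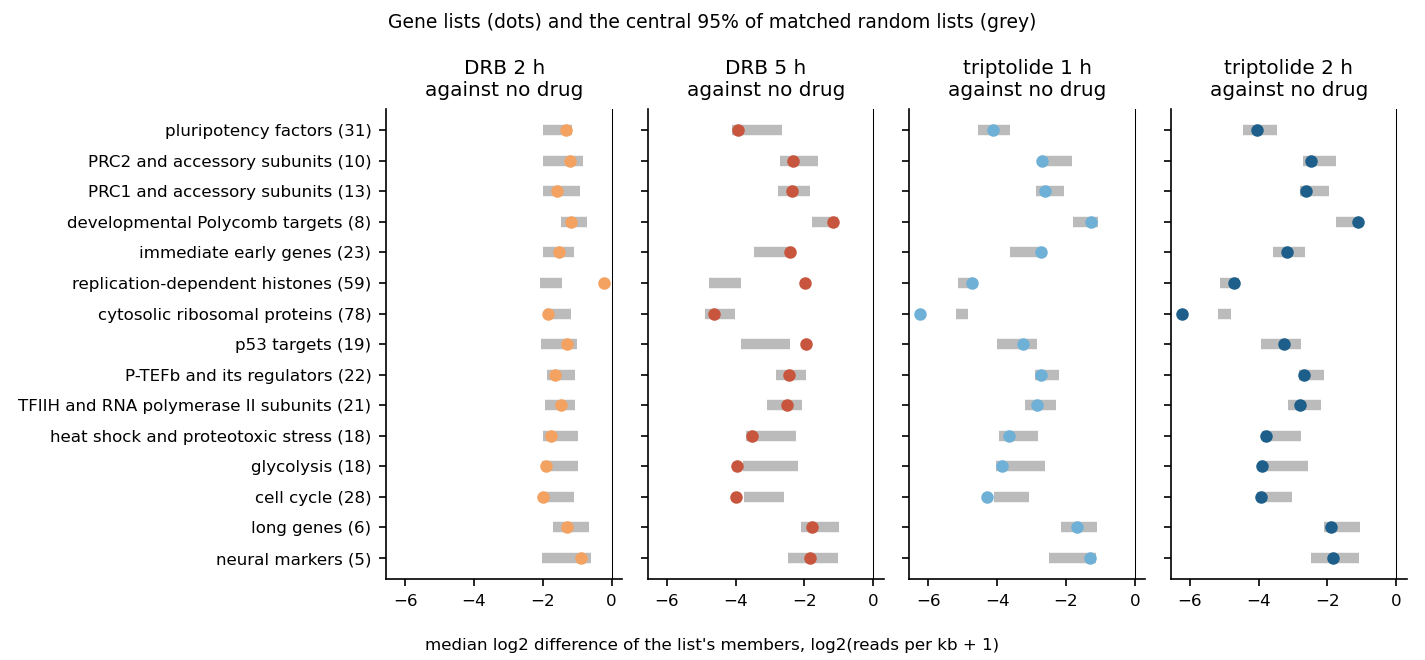
Dots show the median log2 difference (log2 of reads per kb plus 1) of each gene list, with the number of members in brackets, in 4 comparisons with no drug, and grey bars the central 95% of 10000 matched random lists. The histone dot lies above the bar at both DRB times, at -0.23 and -1.98, although both medians are positive under both rescalings; where at least 50% of members are listed at 0, as for ribosomal proteins at both triptolide times (45 and 49 of 78), a dot reflects the level without drug and is not read as a response.

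Triptolide for 1 h, which blocks initiation, left Pou5f1, Sox2, Nanog, Actb, Suz12 and Eed listed at 0, and Myc at 0.602 against 22.7 reads per kb. The median gene was at 0% of its level without drug, with 5079 of 8560 genes listed at 0. Ezh2 was at 13.1% of no drug and Ext1, a long gene for a heparan sulfate enzyme, at 12.3%; both were higher under both rescalings. Hexim1 was at 7.81%, and higher with equal quantiles. Jarid2 was at 1.55%, Cbx7 at 2.14%, Gapdh at 0.421 against 132 reads per kb, and Mepce and Atf4 were listed at 0. Of 8773 genes 7715 were lower by at least 1 log2 unit and 69 higher, with a median of -1.98. Quantile normalization gave 2827 lower and 1161 higher. A minimum of 20 net reads in 1 condition gave 6604 and 14, and a pseudocount of 10 gave 1381 and 1.

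Ribosomal protein genes kept 0.546% of net reads after 1 h of triptolide, with 45 of 78 listed at 0, among them Rps24 and Rps12, and lists matched on the level without drug kept 0.723% (central 95% from 0.210% to 6.26%). Histone genes kept 2.34%, with 47 of 59 listed at 0, and Hist1h1b was at 0 against 309 reads per kb. Pluripotency genes kept 0.922%, PRC2 genes 1.93% with all 10 lower, PRC1 genes 1.34% with all 13 lower, and developmental Polycomb targets 8.70%. Cell cycle genes kept 0.545%, glycolysis genes 0.394%, heat shock genes 0.274% and p53 targets 0.655%. P-TEFb and TFIIH genes kept 1.54% and 2.43%, and Eno1, a glycolytic enzyme gene, was at 0.799%. Immediate early genes kept 4.14%, with 22 of 23 lower, and their median of -2.72 lay above the random lists (random median -3.29), a call that 1 of 7 other settings kept. Long genes kept 7.96% and neural markers 6.36%, against 2.33% for primitive endoderm and 1.32% for fibroblast and feeder markers; the long gene median of -1.66 turned positive under both rescalings and the neural median of -1.29 with equal quantiles. Without the member with most reads, histones kept 1.47%, pluripotency genes 0.290%, PRC1 genes 0.877%, developmental targets 4.42%, p53 targets 0.426%, heat shock genes 0.0587%, cell cycle genes 0.227%, long genes 4.04%, neural markers 3.42%, and primitive endoderm and fibroblast and feeder markers 0. Higher values were seen at Trappc6a, a vesicle-tethering subunit gene, at 3.50 times (1.55 to 8.89) no drug, Chmp6, an ESCRT-III subunit gene, at 2.68 times, Hist1h4i at 2.25 times (1.10 to 4.88), and 0610039K10Rik at 20.0 against 6.32 reads per kb.

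After 2 h of triptolide the median gene was at 0.482% of its level without drug (5.00% with equal medians and 14.1% with equal quantiles), with 4234 of 8560 genes listed at 0. Pou5f1, Sox2, Myc, Eed, Hexim1, Cdkn1a, Actb and Gapdh were listed at 0, Nanog was at 0.840 against 30.0 reads per kb, and Jarid2 at 2.28%. Ezh2 was at 46.0% (33.6 to 62.4) of no drug, and higher under both rescalings, and Suz12 was at 6.61%, and higher with equal quantiles. Of 8773 genes 7636 were lower by at least 1 log2 unit and 76 higher, with a median of -1.92. A minimum of 20 net reads in 1 condition left 6562 lower and 9 higher, and a pseudocount of 10 left 1362 and 4. Scaling to equal medians gave 5264 lower and 754 higher, and quantile normalization 2453 and 1176.

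Ribosomal protein genes kept 0.417% after 2 h of triptolide, with 49 of 78 listed at 0, Rps24 and Rpl3 among them, the latter at 254 reads per kb without drug, and lists matched on the level without drug kept 0.933% (central 95% from 0.293% to 8.83%). Histone genes kept 3.35%, with 44 of 59 listed at 0 and Hist1h1b at 0, but 1.63% (1.21 to 2.16) without Hist1h4i. Pluripotency genes kept 0.509%, PRC2 genes 4.16% with 8 of 10 lower, PRC1 genes 2.37% with all 13 lower, and developmental Polycomb targets 8.70%, with Otx2, a neural transcription factor, lower than without drug but higher with equal quantiles. Immediate early genes kept 3.32%, p53 targets 1.08%, glycolysis genes 0.561%, cell cycle genes 1.37%, heat shock genes 0.766%, P-TEFb and TFIIH genes 3.10% and 3.25%. Long genes kept 2.77%, primitive endoderm markers 3.65%, neural markers 2.60% and fibroblast and feeder markers 0. Without the member with most reads, PRC2 genes kept 2.64%, developmental targets 3.21%, immediate early genes 2.03% and primitive endoderm markers 0. The medians of the PRC1 list and the developmental targets, -2.61 and -1.12, were positive with equal quantiles. Higher values were seen at Hist1h4i, at 98.9 against 22.4 reads per kb or 4.42 times (2.33 to 9.08), Mrps12, a mitochondrial ribosome gene, at 2.52 times (1.53 to 4.28), Btn1a1, a butyrophilin gene, at 2.10 times, and 0610039K10Rik at 4.33 times. Mdm2, chosen after its values were seen, was at 0.229 against 10.9 reads per kb.

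DRB for 5 h against 2 h asks how labelled reads differed between the 2 times, where depth cannot be separated from transcription. Mt1, a metallothionein gene, Socs3, a STAT3 feedback inhibitor, Trim28, a heterochromatin cofactor, Tubb5 and Utf1 were listed at 0 at 5 h, against 84.1, 58.5, 48.1, 81.3 and 40.1 reads per kb at 2 h. Sox2 at 5 h was at 38.8% (27.4 to 54.1) of its 2 h value, a direction that turned with equal quantiles. Junb was at 10.6%. Suz12 was at 78.8% (45.3 to 136) and Cdkn1a at 74.1% (39.4 to 137), differences not detectable at this depth. Higher at 5 h were Glis1, a zinc finger factor gene, at 15.7 times (9.31 to 28.4) and Tmem40 at 11.2 times. The pluripotency list kept 6.92% of its 2 h reads, against 17.4% (central 95% from 8.23% to 40.9%) in lists matched on the 2 h level, and 4.47% without its top member. Cell cycle genes kept 7.51%, against 18.1% (7.64% to 45.1%), and glycolysis genes 4.19%, against 17.6% (5.97% to 47.9%); without their top members they kept 4.92% and 1.32%. p53 targets kept 70.9%, against 17.7% (6.40% to 46.0%), but 29.0% without Mdm2. The histone median, -1.75, lay above the random lists (random median -2.27); 3 of 7 other settings lost that call, a pseudocount of 10 put the list below the random lists, and with equal quantiles the median was 0, while the 27.5% of 2 h reads that histones kept lay within lists matched on level. Genes lower by at least 1 log2 unit numbered 2607 and genes higher 99, against 3644 and 787 with equal medians and 2086 and 925 with equal quantiles.

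Between 1 h and 2 h of triptolide 266 genes were lower by at least 1 log2 unit and 294 higher, and the median difference was 0; equal medians gave 1391 lower and 2111 higher, and equal quantiles 1292 and 1657. Chmp6 was at 8.35 reads per kb at 1 h and listed at 0 at 2 h, and Klf2, a pluripotency factor gene, and Hist1h2ae were listed at 0 at 1 h and at 4.19 and 14.2 reads per kb at 2 h. Abcg1, a sterol transporter gene, was at 19.8 times (7.42 to 74.3) its 1 h value and Polr2g, an RNA polymerase II subunit gene, at 5.67 times. The long gene and neural marker medians, -0.16 and -0.24, lay below the random lists; of 6 other settings, 2 lost the first call and 4 the second.

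DRB against triptolide at 2 h compares the blocks of elongation and initiation at 1 time, though at different doses. Trim71, a stem cell gene, was at 26.9 with DRB and 0.140 reads per kb with triptolide, a ratio of 192 (97.3 to 446), and Nanog was 9.5 times (4.11 to 27.0) higher with DRB. Ezh2 was at 1.19 times (0.840 to 1.69), not a detectable difference, and Suz12 at 2.20 times (1.16 to 4.36), which turned lower under both rescalings. Zmat3, a p53 target, was at 9.81 reads per kb against 0, and Mdm2, also of the p53 target list, at 104 times (44.2 to 321). Tbx2, a developmental target, was at 0.50 times (0.171 to 1.32). Histone genes were at least 1 log2 unit higher with DRB in 56 of 59 members, with a median difference of 4.38, and the ribosomal protein median was 4.26; 44 of 59 and 49 of 78 members were listed at 0 with triptolide. The developmental Polycomb target median, -0.13, lay below (random median 0.30), but inside without a filter and with at least 20 net reads. The summed net reads of this list went the other way, at 43 with DRB against 22, or 1.95 times (1.14 to 3.43). Without Pax6 they were equal, at 100% (50.1 to 200). Of 8773 genes, 2911 were at least 1 log2 unit higher and 91 lower with DRB, and 4077 and 848 with equal medians, 2338 and 1225 with equal quantiles.

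Across 8634 genes the DRB 2 h and triptolide 2 h differences from no drug had a Pearson r of 0.577 and a Spearman rho of 0.614. Simulated columns with no change that share the control column, all at the no-drug read numbers, gave an r of 0.4998, with 0.547 the highest, and a covariance of 0.042 against 0.668. With equal medians the observed r was 0.246 and with equal quantiles 0.320, over 8773 genes, both below that simulated r, which was not recomputed under these scalings. In both comparisons 5633 genes were lower, against 5048 with independent draws, and 37 were higher, against 1.67. Both calls depend on the same gene's no-drug value, so some excess over independent draws arises in any case and decides nothing. DRB at 2 h and 5 h gave an r of 0.648 and triptolide at 1 h and 2 h 0.923. Among 8560 genes with signal without drug, 47.3% were listed at 0 after 5 h of DRB, and 59.3% and 49.5% after 1 h and 2 h of triptolide. For these the difference repeats the level without drug, which raises r by itself. The simulated columns lack this floor, so none of these r values measures a shared response. Every comparison uses the same control column, which cannot be split, so the part of each excess that comes from that column is unknown. Genes are not independent replicates.

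After 1 h of triptolide genes over 200 kb kept 17.1% (16.8 to 17.4) of their net reads, while the 5 shorter classes kept between 2.57% and 3.33%, and after 2 h genes over 200 kb kept 3.33%. After 2 h of DRB the classes kept 29.9% under 10 kb, 27.0% from 10 to 25 kb, 23.1% from 50 to 100 kb and 27.1% over 200 kb. Across 8458 genes the Spearman rho of length with log2 difference was 0.071 for 2 h of DRB, 0.207 for 5 h, 0.203 for 1 h of triptolide and 0.203 for 2 h. With the ratio in place of the log2 difference, rho was 0.096 for 5 h of DRB, 0.055 for 1 h and 0.093 for 2 h of triptolide. For 2 h of DRB it was -0.065, the opposite sign, and the rho of the log2 difference was also negative with a pseudocount of 0.1, with values above 10 and with equal medians.

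**Figure D4:**
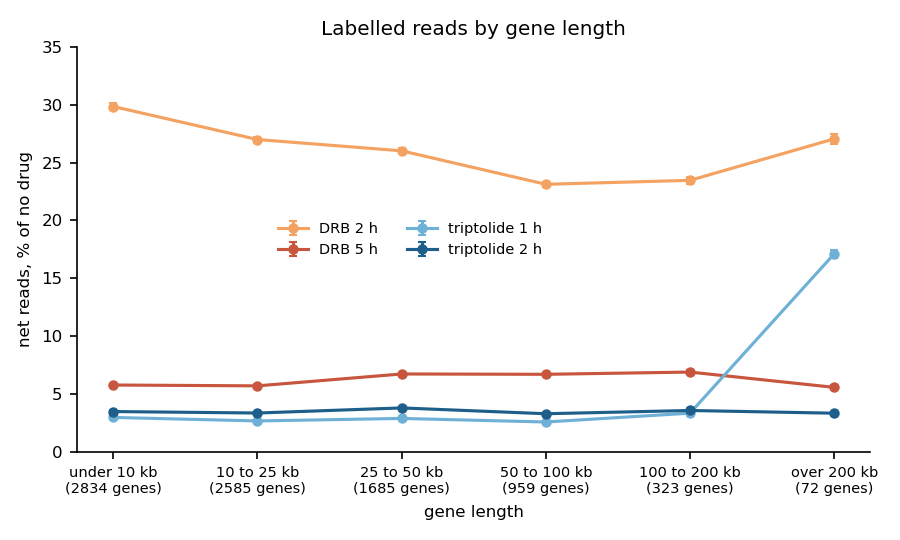
Points show net reads as percent of no drug in 6 classes of gene length, with the number of genes in each class and exact 95% Poisson intervals of the ratio. The triptolide 1 h line is at 17.1% in the 72 genes over 200 kb and between 2.57% and 3.33% in shorter classes.

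Of the genes with higher values after 2 h of DRB, several lay beside a strongly transcribed gene. Cables2, chosen after its values were seen, and Rbbp8nl lie within 50 kb of the 3' end of Rps21, at 0.095 kb and 19.2 kb, and Colec11 lies 7.48 kb from that of Rps7. Cables2 and Rbbp8nl lie on the strand opposite to Rps21 and Colec11 on the strand of Rps7, and whether reads were counted by strand is not stated.

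**Figure D5:**
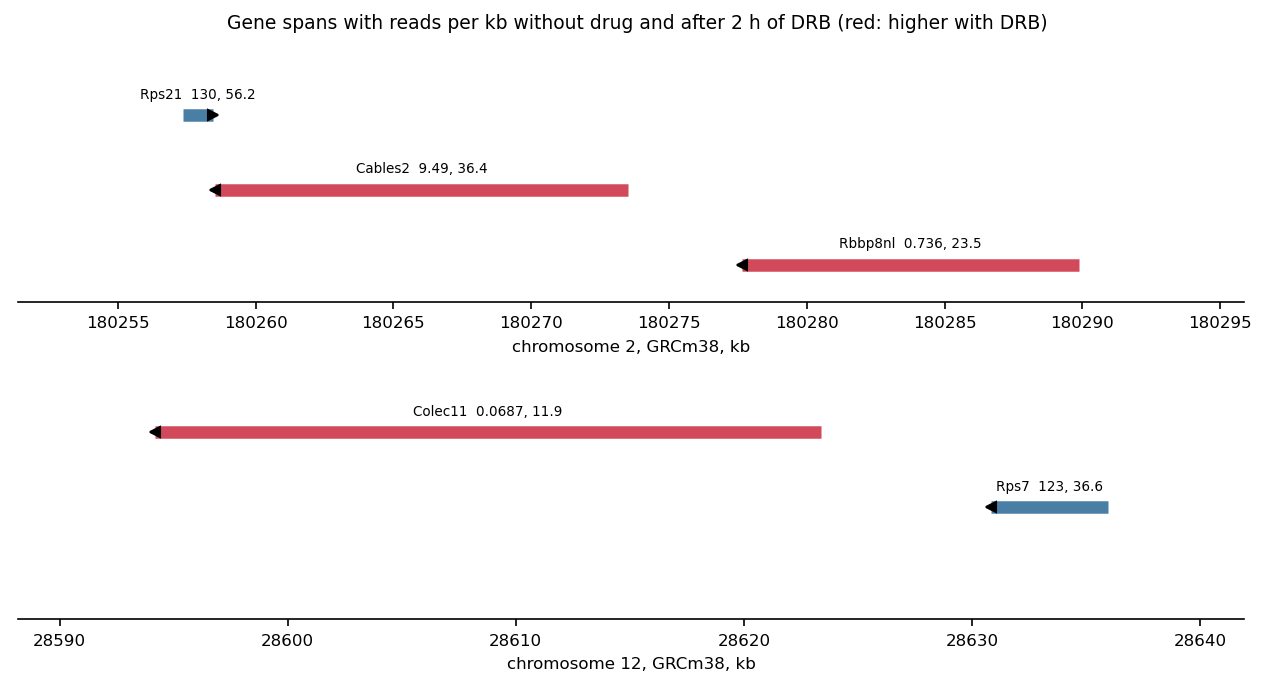
Bars show the spans and arrows the direction of transcription of genes at 2 loci, with positions in kb of GRCm38 and with reads per kb without drug and after 2 h of DRB beside each name. Colec11 stands at 0.0687 and 11.9 reads per kb beside Rps7 at 123 and 36.6, and Cables2 at 9.49 and 36.4 beside Rps21 at 130 and 56.2.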

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

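The tests of elongating polymerases, of a few genes with very many reads, of tRNA genes as the source in most genes and of counting error in the triptolide 2 h column were chosen after the results were seen; the other tests were set before. Values are ratios to no drug with exact 95% Poisson intervals, on the deposited scale and without replicates.

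Genes were taken that the naming rule selects in at least 1 of the 7 comparisons and that had at least 20 net reads without drug. Of these, 8 were higher than without drug after 2 h of DRB and lower in another column, with Poisson intervals that exclude 1. Those intervals leave out background subtraction, and the naming rule favours extreme ratios in these same columns. The difference between the columns was not tested against replicate spread. Values lower than without drug were the rule after 2 h of triptolide, in 8433 of 8773 genes. Mdm2 was at 2.18 (1.87 to 2.55) after 2 h of DRB and at 0.0210 after 2 h of triptolide. Zmat3, a p53 target, was at 1.23 (1.03 to 1.46), against 0.360 after 5 h of DRB and 0 after 2 h of triptolide. With columns scaled to equal medians, Zmat3 after 5 h of DRB was higher than without drug. Cables2 was at 3.84 (3.19 to 4.65) and Ccdc84 at 1.80 (1.45 to 2.24), against 0.00704 and 0.0148 after 2 h of triptolide. After 5 h of DRB Ccdc84 was at 0.615, but higher than without drug with equal medians. Junb was at 3.92 (2.84 to 5.50), against 0.417 after 5 h of DRB and 0 after 2 h of triptolide, and Socs3 at 2.52 (1.97 to 3.25), against 0 and 0.0326. The value of Junb after 5 h of DRB also turned higher than without drug with equal medians. Nlrp12 was at 6.36 (4.79 to 8.58) and St5 at 2.87 (2.46 to 3.35), against 0.232 and 0 after 2 h of triptolide. With equal medians Nlrp12 after 2 h of triptolide was higher than without drug, so its opposite directions rest on the deposited scale.

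In 97 genes with at least 20 net reads after 2 h of DRB, reads were at least 2 times those without drug. Simulated unchanged columns, 100 in number, gave at most 36 such genes. They were drawn at the no-drug reads, so a gene with none or very few could not pass in them. Background subtraction was not drawn either, so counting error stays open. Reads shared with an overlapping strongly transcribed gene were excluded as the whole cause, being possible in 1 gene or 1.03% (0.182 to 5.61). A candidate explanation is transcription past the 3' end of a strong neighbour: 44 genes or 45.4% lay within 50 kb on the 3' side of a gene in the top 5%, against 17.5% (10.3 to 24.7) in lists matched on level and length. On the 5' side the share was also above the matched lists, at 30.9% against 15.5% (9.28 to 23.7), so nearness to strong genes on either side stays open. Colec11 lies on the strand of its neighbour Rps7, but Cables2 on the strand opposite to Rps21, where the explanation needs reads counted without regard to strand, which is not stated, while Mdm2 has no such neighbour on either side and Socs3 and Nlrp12 have one on the 5' side alone, and no biological explanation was tested.

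After 1 h of triptolide, 72 genes over 200 kb kept 17.1% of their net reads, against 2.81% in 7043 genes under 50 kb, an excess of 6.10 times that was 0.941 times after 2 h. Negative values set to 0 in weak genes were excluded as the whole cause, since short genes matched on level kept 5.83% (3.22 to 10.1). The 5 genes with most reads were excluded as the whole cause too, since without them the long genes kept 12.5% (12.2 to 12.8). The median long gene kept 13.1%, against an upper end of 3.06% of the central 95% of matched lists. Short genes matched on reads per kb have fewer reads and were more often listed at 0, so that gap between medians decides nothing. Polymerases already elongating when the drug was added may account for the excess at 1 h and its absence at 2 h, which that explanation needs; it is a hypothesis found and tested on the same data, and the background subtraction in each column stays open.

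In 45 genes with at least 20 net reads after 2 h of triptolide, the value was no lower than without drug. A simulation of counting error gave 0 such genes but could not have given any, and decides nothing. In the triptolide 1 h column the summed reads of these genes were 127% (117 to 138) of their sum without drug. Lists of 44 genes matched on no-drug reads and length had 38.1% (24.5 to 53.4). Counting error in the triptolide 2 h column was therefore excluded as the whole cause for the set. A sum can be carried by part of its genes, so this error stays open in single genes. Some, such as Cdca3 and Mrpl45, had fewer reads at 1 h than without drug, and others had more. A tRNA gene, read by RNA polymerase III, in or within 1 kb of the gene was seen in 3 of them, BC107364, Btn1a1 and Aloxe3, or 6.67% (2.29 to 17.9), above the upper end of 4.44% of the central 95% of matched lists, and may account for those genes. It was excluded as the source in most of the 45 genes, since its share lies below 50%. For the others the source stays open, with no biological explanation tested. The open sources include counting error without drug and, in single genes, counting error after 2 h of triptolide.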

How the results depend on the processing

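The setting with at least 20 net reads, the percent of reads kept beside matched lists and lists without their top member were chosen after the data were seen; the others were set before. Of 111 main values under other settings, 33 stayed within their limits, 75 moved and 3 reversed. Of 1094 values of named genes 31 reversed, all under a rescaling. This number leaves out the reversals given with the results flagged for a closer look. Of 133 calls of gene lists 102 stayed, 30 were lost and 1 reversed. Of the 20 list calls by median, 11 concern lists with at least 50% of members listed at 0 in a column, where the median follows the level in the other column, so those calls are not used and their stability says nothing; of the other 9, those of histones at both DRB times held under all 7 settings. Where values moved, the cause was not tested, except that pseudocounts, filters and rescalings by construction change how small values or whole columns count. Comparisons are listed in the order DRB 2 h, DRB 5 h, triptolide 1 h and triptolide 2 h against no drug, DRB 5 h against 2 h, triptolide 2 h against 1 h, and DRB against triptolide at 2 h.

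A pseudocount of 10 gave 669, 1315, 1382, 1366, 250, 8 and 315 genes past the size rule, against 5993, 7593, 7784, 7712, 2706, 560 and 3002. It gave length rho of 0.159, 0.241, 0.239 and 0.237, a correlation of the 2 drugs at 2 h of 0.801 against 0.582, and put the histone list at percentile 0.28 for DRB 5 h against 2 h. A pseudocount of 0.1 gave 6077, 3462 and 6427 genes in the last 3 comparisons, rho of -0.033, 0.156, 0.146 and 0.149, and a correlation of 0.369. Values above 10 gave 1264, 1469, 1482, 1485, 1158, 185 and 1230 genes, with fewer genes tested, median levels of 21.95% and 0% of no drug for DRB 2 h and 5 h, rho of -0.052, 0.088, 0.153 and 0.165, a correlation of 0.326 and 12 list calls against 20. With no filter the median levels were 21.4%, 2.78% and 1.73% for DRB 2 h, DRB 5 h and triptolide 2 h, rho 0.301, 0.395, 0.410 and 0.4001, and the correlation 0.802. With at least 20 net reads 322 genes passed for triptolide 2 h against 1 h, the median levels were 1.71% for DRB 5 h and 0.989% for triptolide 2 h, rho 0.206, 0.438, 0.446 and 0.439, and the correlation 0.523.

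Scaling to equal medians moved the median gene by 0.98, 0.63, 0.41, 0.59, -0.14, 0 and 0.26, and quantile normalization by 1.152, 1.46, 1.42, 1.49, 0.42, 0 and -0.38. Equal medians gave 3184 genes for DRB 2 h (2104 lower and 1080 higher, against 5800 and 193), 4431, 3502 and 4925 in the last 3, median levels of 73.5%, 10.9% and 5.00% for DRB 2 h, DRB 5 h and triptolide 2 h, rho of -0.044, 0.145, 0.136 and 0.138, a correlation of 0.246 and 35 list calls. Quantile normalization gave 1321, 3410, 3988, 3629 and, for triptolide 2 h against 1 h, 2949 genes, median levels of 81.6%, 32.5% and 14.1%, rho of 0.015, 0.163, 0.143 and 0.140, a correlation of 0.320 and 40 list calls.

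Beside those given with the results flagged for a closer look, log2 differences that reversed with equal medians were Sox2 1.46, Ezh2 0.75, Eed 0.76, Myc 1.21 and Hist2h2ab 0.086 for DRB 2 h, Sox2 1.35, Suz12 0.0077, Ezh2 1.01 and Cdkn1a 0.71 for DRB 5 h, Ezh2 0.31 and Ext1 0.23 for triptolide 1 h, Ezh2 1.83 for triptolide 2 h, Ezh2 0.26 for DRB 5 h against 2 h, and Suz12 -0.28 for DRB against triptolide. With equal quantiles they were Sox2 0.89, Ezh2 0.56, Eed 0.54 and Myc 0.80 for DRB 2 h, Sox2 1.05, Suz12 0.54, Ezh2 1.21 and Cdkn1a 1.12 for DRB 5 h, Ezh2 0.94, Hexim1 0.75 and Ext1 0.85 for triptolide 1 h, Ezh2 2.14, Suz12 0.37 and Otx2 0.58 for triptolide 2 h, Sox2 0.16 and Ezh2 0.64 for DRB 5 h against 2 h, and Suz12 -0.77 for DRB against triptolide.

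No paired analysis was possible because the columns carry no replicate numbers. With 1 column per condition, leaving out replicates, fits of spread or of 2 conditions alone, self-contained list tests, list tests with an estimated correlation, other splits of the samples and labelled values without subtraction were not possible. Scaling to mitochondrial genes was not possible because they are not in the table, nor was another promoter window, for want of a genome sequence. Genes listed at 0, which give no fold, were 47.3% after 5 h of DRB and 59.3% and 49.5% after 1 h and 2 h of triptolide, and whether depth or transcription sets these shares was not tested.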

Other observations

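The long genes with most labelled reads after 1 h of triptolide, chosen after their values were seen, were Mad1l1, a mitotic checkpoint gene, with 976 net reads, Msi2, an RNA-binding protein gene, with 890, Agap1 with 829, Snd1 with 631, Nav2 with 530 and Tenm4 with 526. After 2 h of triptolide Mad1l1 had 24 net reads, Msi2 127, Agap1 14, Snd1 24, Nav2 50 and Tenm4 239.

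The overlap of genes with retained reads under the 2 drugs was counted against lists of 44 genes matched on no-drug reads and length, a test chosen after the overlap was seen, since both sets favour low values in the same no-drug column. Of the 45 genes with no fewer reads after 2 h of triptolide than without drug, 27 were among the 97 genes with at least 2 times the reads after 2 h of DRB, against 5 (2 to 8) in the matched lists, and 43 had more reads after 2 h of DRB than without drug, against 13 (9 to 17). Matching on the no-drug reads as counted does not remove error in that column, which would raise both ratios of a gene. The matched genes were not chosen for their triptolide reads, so these counts decide nothing about retention shared by the 2 drugs. Median net reads of the 45 genes were 17 without drug and 29 after 2 h of triptolide. Olfactory receptor genes above 0 numbered 8 of 1108 without drug, 8 and 13 after 2 h and 5 h of DRB, and 18 and 12 after 1 h and 2 h of triptolide.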
